A study of Mus musculus with 28 samples.

How the data were processed

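Single cells of the adult mouse subependymal zone (SEZ), the neurogenic niche along the lateral ventricles, were profiled by SORT-seq, which joins fluorescence-activated sorting to the CEL-seq protocol on 384-well plates, and were read on a NextSeq500 with 75 bp paired reads. The 28 libraries form 7 sorts with 4 libraries each. Troy-GFP cells came from mice with a GFP reporter in the gene of Troy, Tnfrsf19, which marks neural stem cells (NSCs) in this study. Ki67-RFP cells came from mice with a red reporter in Mki67, a gene of dividing cells. Day-2 and day-60 tdTomato cells came from mice in which tamoxifen, given once at 5 mg, switched on tdTomato in cells that expressed Mki67, and were taken 2 or 60 days later. A mixed day-60 sort also held tdTomato cells of the olfactory bulb and cells bound by an antibody to O4, an antigen of oligodendrocytes. GLAST/EGF cells were sorted on an antibody to GLAST (the protein of Slc1a3) and/or on binding of labelled EGF. Prom1/CD24 cells were sorted with antibodies to the ventricle-contact marker Prom1 and the neuroblast marker CD24. Mice were 8 to 10 weeks old, against 16 to 19 weeks in the day-60 sort and 8 to 19 weeks in the mixed day-60 sort. The labels do not say how many mice gave each library. The 4 libraries of a sort hold 96 wells each, as many as 1 plate of 384 wells, so p-values may measure only technical spread.

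According to the submitters' processing notes, reads were mapped with BWA 0.6.2-r126 to mm10. The deposited tables give, for each gene and cell barcode, an estimate of transcript molecules, a unit recorded here as other: it is neither a raw read count nor a value scaled between wells. Of 4801006 values above 0, 4800995 equalled the random-barcode collision correction of a whole number of observed barcodes out of 256, within 1e-06, and 11 stood at the value for saturation. The tables held 17690 gene rows, 87 rows of ERCC spike-in RNA and 0 rows of mitochondrially encoded genes. Symbols were kept as deposited, with the chromosome added where 1 symbol stood on more than 1 chromosome (7 symbols). ERCC rows stayed out of library sizes and tests. Their share was 6.57% to 17.7% of all transcripts outside the Prom1/CD24 libraries and 44.3% to 56.8% within them. Gene positions were read from GENCODE M21.

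A well counted as a cell with at least 1000 estimated transcripts over gene rows. Cells were sorted 1 per well, so no doublet caller was used. The labels name no cell types, so cell types were rebuilt here. Cells of all libraries were scaled to 1 total, logged and clustered with scanpy 1.11.5 and igraph 0.11.9 on the 2000 most variable genes (without cell cycle and ribosomal protein genes), 30 principal components, 15 neighbours and Leiden resolution 1.0, with the seed 7 and no batch integration. Each cluster took the name of the cell class, out of 10 fixed marker sets, with most markers among its leading genes, or stayed unnamed. As an exception, the name pericyte-like was withheld from clusters led by fibroblast genes such as Dcn, Lum and Col1a2. Names end in "-like" since they rest on transcripts alone. The NSC-like markers are shared by quiescent NSCs and astrocytes, so that name does not tell these apart. Class shares were compared with exact 2-sided permutation tests of 4 against 4 libraries, for which 0.0286 is the smallest p, and adjusted over all classes and sort comparisons.

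For each library, transcripts were summed over passing cells (or over NSC-like cells, where at least 5 per library and 3 libraries per group were found). Genes needed about 10 transcripts in a library of median size in at least 4 libraries and 15 in all. Sums were scaled by trimmed mean of M values, written out in R 4.3.3, and tested with limma voom 3.58.1. Adjusted p is Benjamini-Hochberg over the genes of a comparison, and a gene passed below 0.05. The planned tests, quasi-likelihood of edgeR and, as an alternative, DESeq2, were not run. An automated check of the tables' format could not read them as counts, and limma was taken in their place before any test had been run. Values of ± beside a log2 fold are standard errors, with n = 4 libraries in each group. Values of ± beside a level or a share are standard deviations over 4 libraries. CPM are transcripts per 1000000, scaled as in the test. Where a gene stood at 0 in every library of a sort, the fold is given as a bound from a floor of 3 transcripts over that sort. Intervals and floors cover counting error only.

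Gene lists were tested with camera of limma at its preset correlation of 0.01, where at least 3 members were tested, adjusted over the lists of a comparison, with camera at an estimated correlation and fry beside it. The lists covered quiescent NSC and astrocyte markers, activated NSC and transit-amplifying progenitor markers, and markers of neuroblasts, mature neurons, ependymal cells, oligodendrocytes, their precursors, microglia and macrophages, endothelial cells, and pericytes and smooth muscle. They also covered S phase genes, G2 and M phase genes, the Notch pathway, BMP and Id genes, Wnt pathway genes, cytosolic ribosomal proteins, lipid metabolism and fatty acid oxidation, glycolysis, immediate early and dissociation stress genes, and the interferon response. Mitochondrially encoded genes had been listed too, and the tables hold 0 of them. Genes named in the text are the 6 genes of the sorts (Tnfrsf19, Mki67, Slc1a3, Egfr, Prom1, Cd24a), the 10 highest and 10 lowest passing genes of the main comparisons (5 and 5 in the others) with a mean log2 CPM of at least 5 and libraries that did not overlap, and up to 4 members per list with the smallest p. Chance alone keeps 2.86% of genes from overlapping in 4 against 4 libraries. The comparisons, lists, markers, cell minimum and most of the other settings tried were set before the data were examined.

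The test was checked on simulated libraries with 200 changed genes per comparison. It found 87.0% to 92.9% of 2-fold changes in all comparisons but that of Prom1/CD24, where it found 62.0%, with 5 to 14 false calls. The simulated dispersion, the squared relative spread beyond counting error, was 0.01 (0.0108 for the mixed sort). These rates do not hold for genes with more spread between libraries, such as Mki67 in Troy-GFP (226 ± 69.5 CPM). Prom1/CD24, with 11 to 20 cells per library, was simulated at 0.01 too, while Slc1a3 (590 ± 210 CPM) and Cd24a (577 ± 182) spread widely there. Its rates may therefore be too favourable. The other settings set at the start were another scaling (median ratio), no filter on low counts, a block for the library number, all sorts in 1 fit, minimums of 500 and 2000 transcripts per cell, cells thinned to 1000 transcripts, observed barcodes in place of corrected estimates, libraries of 1 flow cell (HVJH2BGXX) alone, 10 NSC-like cells per library, Leiden resolution 0.5 and each library left out in turn. A term for the flow cell, limma-trend, the ribosomal RNA precursor gene Rn45s left out, a cycling measure from mitotic genes alone, and a comparison of NSC-like cells of GLAST/EGF and Troy-GFP were added after the data had been seen. NSC-like cells of day 60 and day 2 were not compared, since the day-2 sort held 6 of them. A barcode list deposited with the series was not used here.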

Results

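SORT-seq measured polyadenylated transcripts in single cells of 7 sorts, each in 4 libraries of 96 wells, 2688 wells in all. Of these, 1789 held at least 1000 estimated transcripts and were analysed as cells, 11 to 89 per library. The study's text states about 1500 good cells out of about 2500 sequenced. Passing cells numbered 311 for Troy-GFP, 216 for GLAST/EGF, 315 for Ki67-RFP, 220 for day-2 tdTomato, 349 for day-60 tdTomato, 314 for the mixed day-60 sort and 64 for Prom1/CD24. Total transcripts per library ran from 419843 to 547720 in Troy-GFP, 365484 to 481546 in GLAST/EGF, 498733 to 575257 in Ki67-RFP and 263535 to 379356 in day-2 tdTomato. They ran from 472002 to 511041 in day-60 tdTomato, 317604 to 473553 in the mixed sort and 77795 to 143795 in Prom1/CD24. Median transcripts per cell lay between 3817 (day-2 tdTomato) and 6218 (GLAST/EGF). The sum of 4 Y-linked genes reached 407 ± 11.4 CPM in Troy-GFP and 311 ± 31.9 in GLAST/EGF and stood at 0 in the other sorts. Xist, the RNA of the inactive X chromosome, stood at 2.37 and 0.653 CPM in those sorts and at 139 to 630 in the others. Comparisons of Troy-GFP or GLAST/EGF with any other sort therefore also compared cells of different sex. The names of the deposited tables placed Troy-GFP libraries 1 and 2 and GLAST/EGF libraries 3 and 4 on the flow cell AHY73KBGXX, gave none for day 2, and placed the remaining libraries on HVJH2BGXX.

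Cell classes differed widely between sorts. NSC-like cells, with astrocyte genes such as Slc1a2, Aldoc and Aqp4, made up 77.1% ± 2.81 of Troy-GFP cells and 81.4% ± 2.35 of day-60 tdTomato cells (n = 4 libraries). In GLAST/EGF they made up 55.4% ± 7.52, beside 32.5% ± 9.09 progenitor-like cells. Neuroblast-like cells, marked by Dcx and Dlx genes, made up 62.4% ± 6.30 of Ki67-RFP and 72.5% ± 2.29 of day-2 tdTomato cells, with 31.6% ± 6.18 and 21.6% ± 2.71 progenitor-like cells. The line between these classes moved with the clustering: in Ki67-RFP, neuroblast-like cells made up 45.01% at a minimum of 500 transcripts, 16.4% at 2000 and 16.8% with cell cycle genes kept, and progenitor-like cells 49.1%, 79.04% and 61.9%. At day 2, keeping cell cycle genes gave 56.3% neuroblast-like and 38.2% progenitor-like cells. Day-60 tdTomato held 0 progenitor-like cells of 349, which allows a share of up to 0.860%. The mixed day-60 sort held 39.7% ± 3.44 oligodendrocyte-like, 23.6% ± 1.63 mature neuron-like, 8.73% ± 3.66 NSC-like, 8.68% ± 2.57 microglia-like and 5.38% ± 0.969 oligodendrocyte precursor-like cells. Its microglia-like share was 1.57% at 500 and 1.39% at 2000 transcripts, where cells led by Cd74 fell in an unnamed cluster. Of the 27 NSC-like cells of the mixed sort, 20 formed a cluster without cells of other sorts, led by Islr, Greb1 and Bai1. Most of them thus shared no cluster with the NSC-like cells of other sorts. Prom1/CD24 cells spread over NSC-like (15.8% ± 9.55), endothelial-like (15.4% ± 7.44), neuroblast-like (12.9% ± 5.22) and further classes, with 2.32% to 12.9% neuroblast-like, 5.83% to 21.9% endothelial-like and 13.4% to 26.5% NSC-like cells over the settings. Each sort or gate sets these shares directly, and depth differed between the sorts. In 25 of 66 tests the libraries did not overlap and the exact 2-sided permutation p took its smallest value, 0.0286. After adjustment over all 66 this became 0.0754, so in this design no class share passed 0.05.

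**Figure D1:**
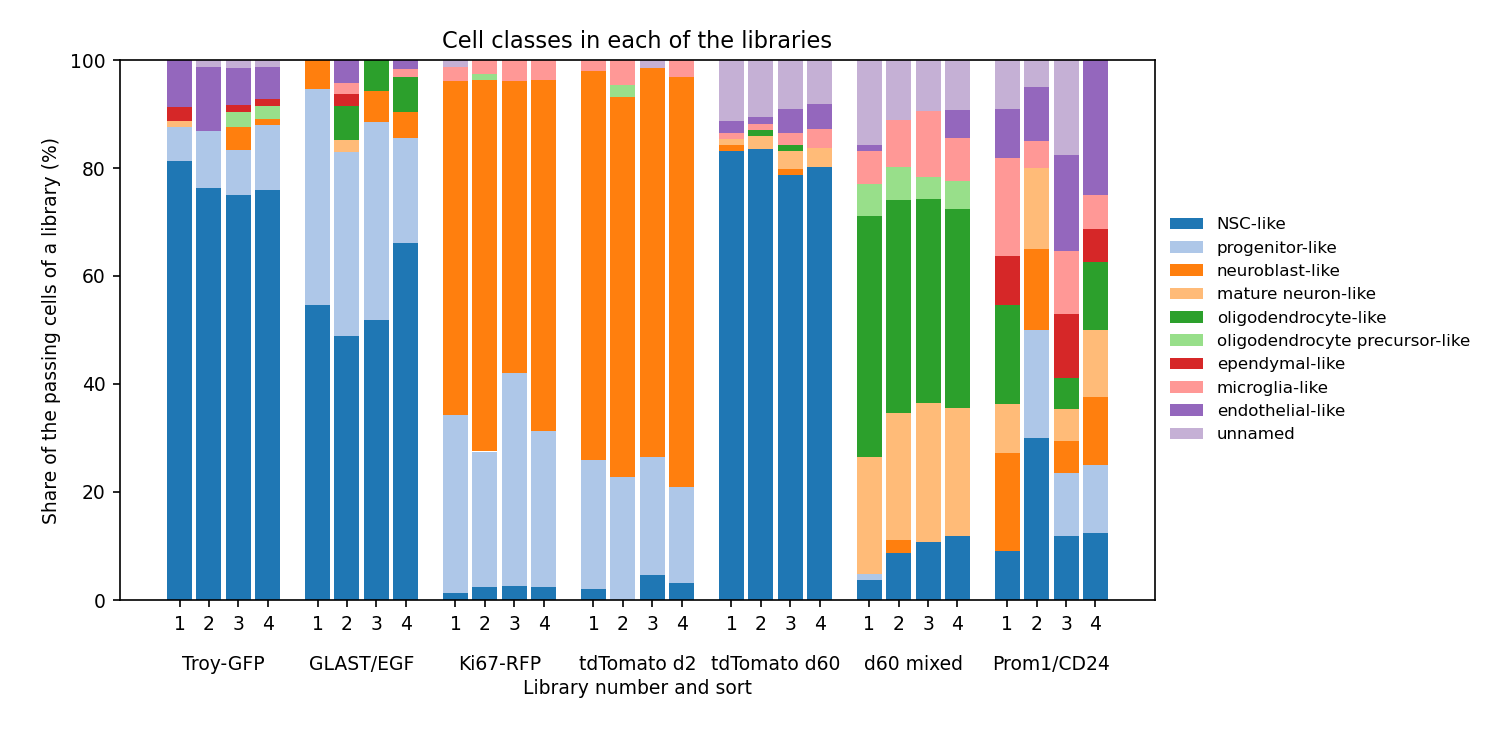
Stacked bars give the share (%) of passing cells in each cell class, for each of the 4 libraries of each sort; libraries are numbered along the horizontal axis. NSC-like cells fill most of the Troy-GFP and day-60 tdTomato bars (means of 77.1% and 81.4%), and neuroblast-like cells 62.4% and 72.5% of the Ki67-RFP and day-2 tdTomato bars; over other clustering settings the Ki67-RFP value ran from 16.4% to 63.04%.

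Of the genes after which the sorts are named, Mki67 and Egfr had their highest means in their own sorts, and Slc1a3 and Cd24a in others; values of Tnfrsf19 and Prom1 overlapped between sorts. Mki67 (chromosome 7, 135689784 to 135716361, mm10), a marker of dividing cells, averaged 639 ± 82.9 CPM in Ki67-RFP and 508 in GLAST/EGF, and stood at 0 in day-60 tdTomato. Slc1a3 (chromosome 15, 8634124 to 8710764), which encodes the glutamate transporter GLAST, averaged 3924 CPM at day 60 and 3146 in Troy-GFP, against 1554 in GLAST/EGF and 179 in Ki67-RFP. Egfr (chromosome 11, 16752203 to 16918158), the EGF receptor, was highest in GLAST/EGF at 363 ± 55.2 CPM. Cd24a (chromosome 10, 43578284 to 43584265), which encodes the neuroblast surface protein CD24, averaged 1828 CPM at day 2, 1119 in Ki67-RFP and 577 in Prom1/CD24. Tnfrsf19 (chromosome 14, 60963875 to 61046490), the gene of Troy, averaged 142 ± 35.2 CPM at day 60, 125 ± 26.3 in Troy-GFP, 98.8 in GLAST/EGF and 82.1 in Ki67-RFP. Prom1 (chromosome 5, 43993620 to 44102032) was low everywhere: its Prom1/CD24 libraries held up to 63.8 CPM and Ki67-RFP libraries 25.5 to 37.6.

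**Figure D2:**
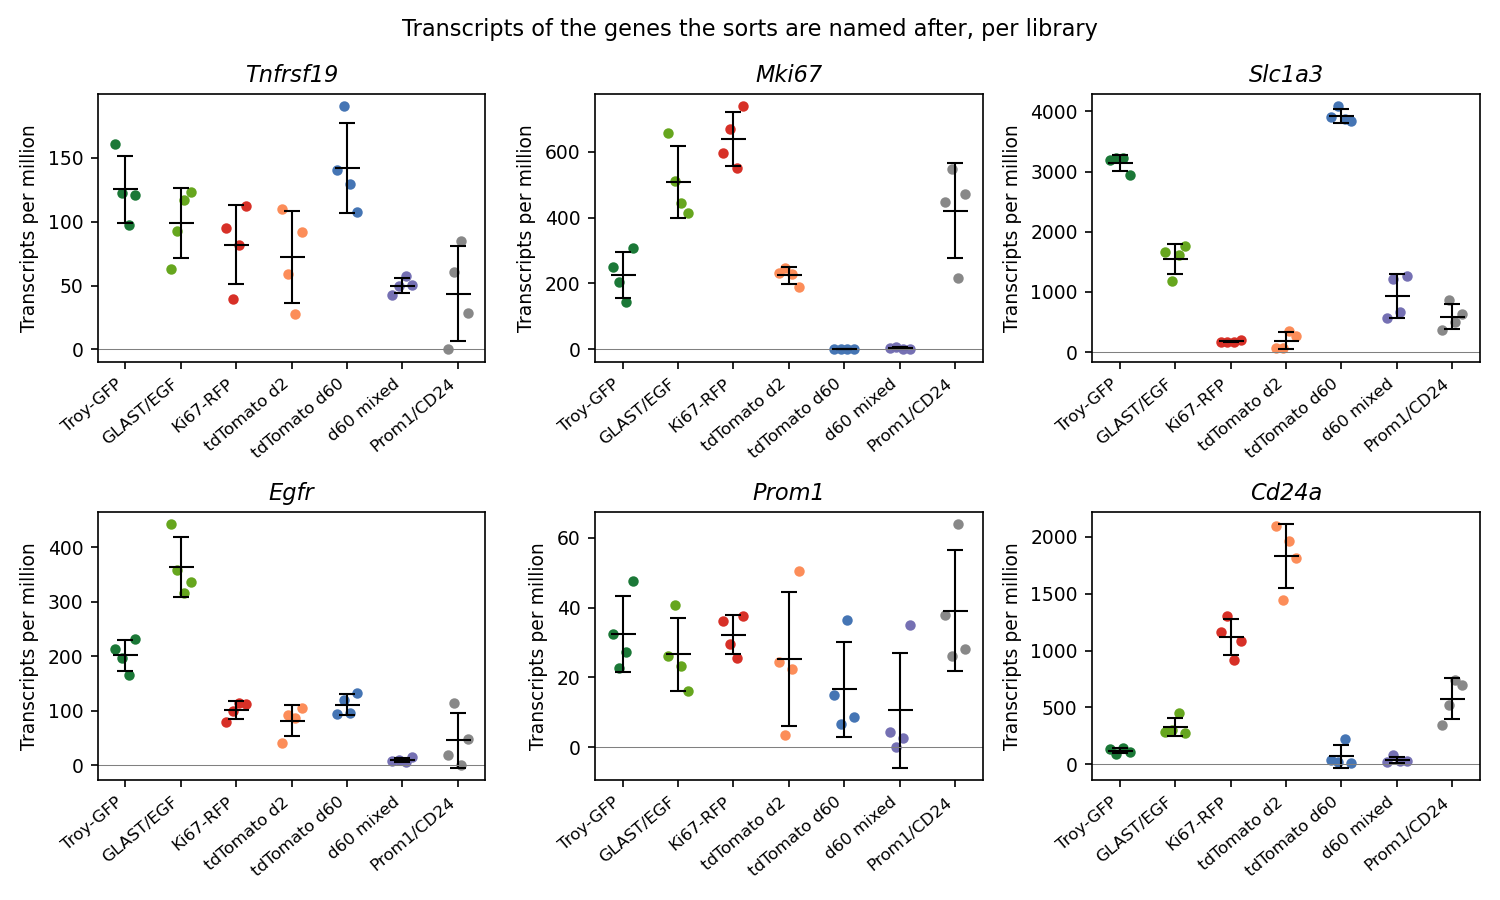
Points give the scaled level (CPM) of 6 genes in each of the 4 libraries of each sort; horizontal marks and bars give the mean and standard deviation. Mki67 is highest in Ki67-RFP (639 CPM) and at 0 in day-60 tdTomato, and Slc1a3 is highest in day-60 tdTomato and Troy-GFP (3924 and 3146 CPM).

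Ki67-RFP against Troy-GFP asked how dividing SEZ cells differ from cells expressing Troy. Of genes high in Troy-GFP cells, Aqp4, the astrocyte water channel, changed by -8.74 ± 0.63 on the log2 scale (3.52 against 823 CPM), the lipoprotein gene Clu by -8.02 ± 0.34, the glycolytic enzyme gene Aldoc by -7.06 ± 0.35 and the BMP target Id3 by -6.57 ± 0.50. Among neuroblast genes, the cytoskeletal genes Stmn2 rose by 4.58 ± 0.40 and Tubb3 by 3.69 ± 0.21, the transcription factor gene Sp9 by 4.46 ± 0.42, and Gad1, which encodes an enzyme of GABA synthesis, by 3.87 ± 0.48. Dlx1as and Dlx6os1, which overlap other Dlx transcripts, gave 5.67 ± 0.58 and 3.99 ± 0.35. Of the sorts' genes, Cd24a rose by 3.13 ± 0.15 and Mki67 by 1.44 ± 0.16, while Slc1a3 changed by -4.22 ± 0.11 and Egfr by -1.09 ± 0.16, all passing with limma. Tnfrsf19 gave -0.78 ± 0.23 (adjusted p = 0.0045), a call lost without Ki67-RFP library 2 (-0.45) and within the flow cell HVJH2BGXX (-0.58). Prom1 did not pass (-0.05 ± 0.28, adjusted p = 0.89). In all, 5005 of 8396 genes passed, 2388 higher and 2617 lower in Ki67-RFP.

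Among the fixed lists, all 24 tested quiescent NSC and astrocyte markers fell (camera adjusted p = 4.0e-22), with Slc1a2 at -4.62 ± 0.10 and Apoe at -4.52 ± 0.15. This call held with an estimated correlation (adjusted p = 0.022). All 25 neuroblast markers rose, such as Stmn1 (2.70 ± 0.10) and Sox11 (2.52 ± 0.11), as did 35 of 35 S phase genes, 56 of 57 G2 and M phase genes and 76 of 78 cytosolic ribosomal protein genes. Their camera adjusted p were 1.8e-18, 6.4e-15, 4.0e-22 and 3.0e-37, and adjusted p = 0.061, 0.061, 0.066 and 0.061 with an estimated correlation. The licensing and replication genes Pcna (1.70 ± 0.13) and Mcm7 (1.79) and the histone gene H2afz (2.34 ± 0.10) were among them. Of 18 activated NSC and progenitor markers 10 rose, Ccnd2 by 1.93 ± 0.09, and 3 fell, among them Rgcc, which stood at 0 in Ki67-RFP (a log2 bound of -6.95). That list gave camera adjusted p = 0.0032, and adjusted p = 0.061 with an estimated correlation. With p adjusted over the list alone, the counts of these lists were 24 lower, 25, 35, 56 and 76 higher, and 12 higher with 3 lower. Lower lists were lipid metabolism (20 of 29 fell, 1 rose; Acsl3 -3.85 ± 0.12), glycolysis (11 of 16 fell), BMP and Id genes (8 of 11 fell, 1 rose; Id2 -3.42 ± 0.16), Wnt pathway genes (12 of 17 fell, 2 rose; Dkk3 -3.41 ± 0.19) and the Notch pathway (10 of 15 fell, 4 rose; Hes5 -2.70 ± 0.19). Their camera adjusted p were 2.0e-06, 0.00012, 0.0042, 0.0042 and 0.033, and adjusted p = 0.061 to 0.079 with an estimated correlation. Interferon response genes (7 of 9 fell, 1 rose) gave 0.0055, and adjusted p = 0.12 with an estimated correlation. When adjusted over the list alone, 21, 11, 8, 12, 10 and 8 of them fell and 2, 0, 1, 2, 4 and 1 rose. Markers of other cell types moved as well: all 10 endothelial markers fell (Flt1 at 0 in Ki67-RFP, a bound of -6.04), 6 of 8 oligodendrocyte markers fell, and all 9 microglial markers rose (C1qb at 0 in Troy-GFP, a bound of 5.61). These gave camera adjusted p of 1.3e-06, 0.0059 and 1.2e-05, and adjusted p = 0.079, 0.14 and 0.061 with an estimated correlation. Adjusted over the list alone, the counts were 10, 7 and 9. Immediate early genes did not pass as a list (adjusted p = 0.11; median 0.26, mean -0.23), with 8 of 22 higher and 5 lower (9 and 5 adjusted over the list alone). Mature neuron markers (3 of 6 higher, 2 lower, as when adjusted over the list alone; median -0.10 but camera and fry upward) and oligodendrocyte precursor markers (3 of 4 lower, also adjusted over the list alone) gave 0.65 and 0.074. After each cell was thinned to 1000 transcripts, 1197 of 1764 genes tested passed, and the calls of the Notch, Wnt and interferon lists ended; that of oligodendrocyte markers ended without the filter on low counts (median -0.70). Thinning moved the median log2 fold by -0.18.

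Day-60 against day-2 tdTomato asked how labelled cells found in the SEZ 60 days after tamoxifen differ from those found after 2 days. Mki67 stood at 0 in all day-60 libraries against 219 CPM at day 2, a bound of -6.97 on the log2 scale. For Top2a, which encodes a topoisomerase of dividing cells, 1.00 estimated transcript was found at day 60 against 1238 at day 2. The neuroblast genes Dcx (-6.76 ± 0.58), Dlx2 (-7.34 ± 0.58) and Tubb3 (-6.35 ± 0.47) fell, and Cd24a changed by -5.50 ± 0.45. The growth factor gene Ptn rose by 7.15 ± 0.44, Aqp4 by 6.73 ± 0.60 and Slc1a3 by 4.80 ± 0.30. Ttr, a gene of the choroid plexus, stood at 0 at day 2 (a bound of 12.09), and 11 of the 12 cells of a cluster led by Ttr came from day 60. Tnfrsf19 rose by 1.31 ± 0.31 (limma adjusted p = 0.0011). Egfr rose by 0.60 ± 0.25 (0.041), a call that ended without day-60 library 2 (0.55) or 4 (0.49) or day-2 library 1 (0.29), 2 (0.62) or 3 (0.63). In all, 5168 of 7648 genes passed, 2658 higher and 2510 lower at day 60. Reads of Rn45s (9.74 ± 0.19), the ribosomal RNA precursor, and Lars2 (6.91) were nearly missing at day 2 alone. Of the passing genes 62 belonged to 615 picked by symbol: Gm with a number, endings in -ps, -rs or rt, symbols on several chromosomes, and Rn45s, Rn4.5s and Lars2. Day-60 mice were older, and the labels name no flow cell for day 2. Labelled cells that had left the SEZ were not part of this day-60 sort. NSC-like cells made up 81.4% of cells at day 60 and 2.48% at day 2. The folds of genes and lists therefore mix differing cell composition with any change within cells, and do not trace the fate of single cells.

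All 22 tested quiescent NSC and astrocyte markers rose (camera adjusted p = 2.7e-13, and adjusted p = 0.13 with an estimated correlation), with Slc1a2 at 4.83, Apoe at 5.71 and the protease inhibitor gene Cst3 at 2.99 ± 0.12. All 32 S phase genes fell (1.3e-14), a call that held with an estimated correlation (adjusted p = 0.0041); Pcna gave -3.50 ± 0.15. G2 and M phase genes fell in 53 of 57 cases with 1 higher, neuroblast markers in 25 of 26 and cytosolic ribosomal proteins in 77 of 79 (Rps26 -2.76 ± 0.12). These gave camera adjusted p of 7.3e-21, 8.8e-14 and 1.8e-29, and adjusted p = 0.13 each with an estimated correlation. Activated NSC and progenitor markers fell in 11 of 16 cases and rose in 2 (0.00069, and adjusted p = 0.077 with an estimated correlation), with Ccnd2, a cyclin gene, at -3.79 ± 0.14. Metabolic lists rose: glycolysis in 16 of 16 cases (Aldoc 5.59) and lipid metabolism in 22 of 28 with 1 lower (Acsl3 3.77), at camera adjusted p of 1.1e-05 and 2.5e-05, and adjusted p = 0.13 each with an estimated correlation. BMP and Id genes (6 of 11 higher, 1 lower; Id3 5.99), Wnt pathway genes (10 of 14 higher, 2 lower) and the interferon response (9 of 10 higher, 1 lower; the MHC gene H2-K1 4.52) gave 0.021, 0.012 and 0.0025. Their values were adjusted p = 0.17, 0.13 and 0.15 with an estimated correlation. With p adjusted over the list alone, every count just given was the same. Oligodendrocyte markers rose in 8 of 9 cases (Car2 4.10) and endothelial markers in 7 of 7 (Cldn5 at 0 at day 2, a bound of 4.12), with equal counts adjusted over the list alone, at 0.011 and 0.00069, and adjusted p = 0.31 and 0.18 with an estimated correlation. The Notch pathway (Hes5 3.46 ± 0.23, Dll1 -4.29), immediate early genes and markers of microglia, mature neurons and oligodendrocyte precursors did not pass as lists (adjusted p = 0.068, 0.83, 0.29, 0.83 and 0.32; immediate early genes pointed upward with camera and downward with fry). In these lists 9, 10, 3, 3 and 3 genes rose and 4, 6, 0, 3 and 1 fell. When adjusted over the list alone, only the microglial count differed, at 2 higher. After thinning, 1247 of 1706 genes tested passed and the Wnt call ended, with the median log2 fold moved by 0.22.

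Day-2 tdTomato against Ki67-RFP asked how cells labelled while dividing 2 days earlier differ from cells carrying the reporter of division at the time of sorting. Mki67 was lower at day 2 (log2 fold -1.53 ± 0.13, 231 against 670 CPM), and Cd24a was higher (0.68 ± 0.10, limma adjusted p = 1.1e-05). Among neuroblast markers the growth-associated gene Nrep (1.56 ± 0.13) and Gad1 (1.53 ± 0.14) rose, while Sox11 fell (-0.71 ± 0.06). The progenitor genes Ccnd2 (-0.91 ± 0.06), Hes6 and Sox4 (-2.13 ± 0.17) fell. Egfr (-0.36, adjusted p = 0.24), Slc1a3 (-0.21, 0.64), Tnfrsf19 (-0.38, 0.42) and Prom1 (-0.68, 0.27) did not pass. The lowest folds were those of Rn45s (-8.25 ± 0.25), Gm5176 (-5.39), Lars2 (-4.21 ± 0.54) and the zinc finger gene Zfp459 (-3.00 ± 0.39), and the highest those of Gm1821 (5.70), the transporter gene Slc23a1 (3.61 ± 0.17) and Rps27rt (2.99). Whether Gm5176, Gm1821 and Rps27rt took up reads of related genes was not tested, so their levels are uncertain. In all, 1982 of 6952 genes passed, 997 higher and 985 lower at day 2, 41 of them among the 615 genes picked by symbol. The labels name no flow cell for day 2, and the mouse lines of these sorts differ. Time since labelling therefore cannot be told apart from mouse line, a batch or reads counted in another way, for these genes or for the lists below.

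Neuroblast markers rose in 16 of 25 cases and fell in 2 (camera adjusted p = 1.8e-05, and adjusted p = 0.30 with an estimated correlation). Activated NSC and progenitor markers fell in 8 of 17 cases and rose in 1 (0.00058, and adjusted p = 0.14 with an estimated correlation). S phase genes fell in 12 of 35 cases and rose in 5 (0.017, and adjusted p = 0.48 with an estimated correlation), among them the DNA ligase gene Lig1 (-1.13). G2 and M phase genes gave 6 of 57 higher and 13 lower and did not pass (0.52). Mature neuron markers rose in 3 of 6 cases (Snap25 1.69 ± 0.21, Meg3 1.86 ± 0.20) and fell in 1 (0.017, and adjusted p = 0.25 with an estimated correlation), a call that ended without the filter on low counts. Ribosomal protein genes went both ways, 28 of 79 higher (Rpl39 1.25 ± 0.08) and 13 lower (Rpsa -1.24 ± 0.10), at 0.0073, and adjusted p = 0.76 with an estimated correlation. Immediate early genes fell in 9 of 15 cases and rose in 2 (Fos -1.54; 0.015, and adjusted p = 0.48 with an estimated correlation). Microglial markers fell in 4 of 12 cases (0.025, and adjusted p = 0.76 with an estimated correlation), and without day-2 library 3 their median turned from -1.20 to 0.11. Adjusted over the list alone, these 8 lists gave 16 and 2, 1 and 8, 5 and 15, 6 and 13, 5 and 1, 29 and 13, 2 and 10, and 0 and 4 genes higher and lower. Quiescent NSC and astrocyte markers (3 of 17 higher, 1 lower, as when adjusted over the list alone) gave 0.30, and 0.028 with a block for the library number. The remaining lists did not pass: Notch (0.52), BMP and Id (0.60), Wnt (0.15), lipid metabolism (0.99), glycolysis (0.17), the interferon response (0.99) and oligodendrocyte markers (0.60). The interferon median was -0.33 while camera pointed upward. In these, 1, 0, 0, 3, 1, 1 and 0 genes rose and 2, 3, 3, 2, 4, 0 and 0 fell. With p adjusted over the list alone, lipid metabolism gave 2 and 1, glycolysis 2 and 4 and the rest the same counts. After thinning, 402 of 1492 genes tested passed, and the calls of ribosomal and immediate early genes ended; with limma-trend those and the S phase, mature neuron and microglial calls ended.

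GLAST/EGF against Troy-GFP asked how cells sorted on a surface marker of NSCs and on EGF binding differ from Troy-GFP cells; both sorts carried Y transcripts. GLAST/EGF held more Egfr (0.85 ± 0.15, 388 against 213 CPM, limma adjusted p = 0.00016), Mki67 (1.19 ± 0.19) and Cd24a (1.47 ± 0.18), and less Slc1a3 (-1.01 ± 0.11). Anln, a gene of cell division, rose by 2.27 ± 0.55 and the neuronal RNA-binding gene Elavl2 by 2.03 ± 0.34; within the flow cell HVJH2BGXX the call of Elavl2 ended. The extracellular matrix gene Thbs4 (-2.90 ± 0.36), the BMP family gene Gdf10 (-2.68 ± 0.41) and the endothelial genes Slco1a4 (-4.99 ± 0.84) and Itm2a (-4.35 ± 0.55) fell. Tnfrsf19 (-0.33, 0.24) and Prom1 (-0.32, 0.50) did not pass. In all, 2379 of 7818 genes passed, 1168 higher and 1211 lower. Within the flow cell HVJH2BGXX, with 2 libraries against 2, 1024 passed.

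Of 24 quiescent NSC and astrocyte markers 23 fell, such as Clu (-1.87 ± 0.10) and Slc1a2 (-1.18 ± 0.08), 33 of 35 S phase genes rose, such as Pcna (1.45 ± 0.15), and 75 of 77 ribosomal protein genes rose. Activated NSC and progenitor markers rose in 12 of 18 cases and fell in 1 (Ccnd2 1.32 ± 0.12, Insm1 1.60, Rgcc -1.76), and BMP and Id genes fell in 5 of 11 (Id3 -1.70, Id2 -1.35). Camera adjusted p were 4.4e-25, 6.2e-21, 8.2e-41, 3.7e-07 and 0.00043, and all 5 calls held with an estimated correlation (adjusted p = 0.045). G2 and M phase genes rose in 40 of 53 cases and fell in 1 (7.2e-14), and neuroblast markers rose in 15 of 22 (7.0e-12; Stmn1 1.35), with adjusted p = 0.14 and 0.089 with an estimated correlation. Lipid metabolism (11 of 29 fell, 1 rose) and glycolysis (10 of 15 fell) gave 0.00035 and 3.7e-05, and adjusted p = 0.057 each with an estimated correlation. Endothelial markers fell in 11 of 11 cases (2.7e-07), the interferon response in 5 of 10 (0.016; B2m -1.37) and Wnt pathway genes in 6 of 17 with 2 higher (0.047), with adjusted p = 0.16, 0.34 and 0.19 with an estimated correlation. When adjusted over the list alone, in the order just given, 24, 0, 0, 1, 6, 1, 0, 11, 10, 11, 5 and 7 genes fell and 0, 34, 77, 13, 0, 43, 16, 1, 0, 0, 0 and 3 rose. The interferon call ended without GLAST/EGF library 3 (median -0.67), and the Wnt call without GLAST/EGF library 1 (-0.54) or Troy-GFP library 1 (-0.32) or 4 (-0.44). Oligodendrocyte markers (0.14, and 0.00018 with a block for the library number), immediate early genes (0.086, and 0.035 with that block), the Notch pathway (0.12), mature neuron markers (0.24) and oligodendrocyte precursor markers (0.30) did not pass. In these, 3 of 10, 7 of 20, 1 of 15, 0 of 4 and 0 of 5 genes rose and 1, 4, 5, 1 and 1 fell; adjusted over the list alone, 4, 8, 1, 0 and 0 rose and 1, 4, 6, 1 and 1 fell. After thinning, 274 of 1360 genes tested passed, and the lipid, interferon and Wnt calls ended.

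Prom1/CD24 against Troy-GFP asked how cells sorted with antibodies to Prom1 and CD24 differ from Troy-GFP cells. The labels do not say whether cells positive or negative for either antibody were taken. Cd24a was higher (2.38 ± 0.22) and Slc1a3 lower (-2.30 ± 0.16), and the myelin genes Mbp (3.88 ± 0.74), Mal (4.26 ± 0.78) and Trf (6.32 ± 1.12), an iron transport gene, were higher. The Notch target Hes5 gave -4.20 ± 0.64 and Crym, which encodes a thyroid hormone binding protein, -4.45 ± 0.81. Ddx3y and Eif2s3y, both on the Y chromosome, stood at 0 in Prom1/CD24 (bounds of -4.46 and -4.03). Egfr gave -2.39 ± 0.63 (limma adjusted p = 0.012) and Mki67 0.98 ± 0.28 (0.016); both calls ended within the flow cell HVJH2BGXX (folds of -2.45 and 0.94, with 2 Troy-GFP libraries), and that of Mki67 also without Prom1/CD24 library 2 (0.79) or 4 (0.88) or Troy-GFP library 2 (0.92) or 3 (0.75). The calls of Mbp (3.91 there), Trf (5.79) and the microglial gene C1qb (7.51) ended there too. Tnfrsf19 did not pass (-1.48 ± 0.54, 0.058). In all, 1477 of 5680 genes passed, 776 higher and 701 lower in Prom1/CD24; without the filter on low counts 3258 were higher and 1324 lower. The count fell to 964 without Troy-GFP library 2 and 958 without Troy-GFP library 3, when 2619 and 2632 genes were tested, and to 779 within the flow cell HVJH2BGXX. These libraries held 64 cells and the highest share of ERCC RNA.

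All 23 quiescent NSC and astrocyte markers fell (Slc1a2 -3.08), 39 of 48 G2 and M phase genes rose (Ccnb1 3.13), and 71 of 76 ribosomal protein genes (Rps15 1.71), 15 of 20 neuroblast markers (Stmn2 3.46) and 16 of 23 immediate early genes (Ier2 2.59) rose. Camera adjusted p were 2.7e-21, 1.1e-21, 3.2e-33, 1.5e-09 and 7.8e-08, and adjusted p = 0.10, 0.12, 0.10, 0.17 and 0.12 with an estimated correlation. Adjusted over the list alone, the counts were 23, 45, 73, 15 and 17. Markers of other cell types rose: oligodendrocytes in 10 of 13 cases, microglia in 7 of 7 (C1qb at 0 in Troy-GFP, a bound of 7.52) and endothelium in 4 of 11 (Ly6c1 2.15). These gave 1.9e-06, 5.8e-07 and 0.0024, and adjusted p = 0.30, 0.14 and 0.38 with an estimated correlation; adjusted over the list alone, 11, 7 and 4 rose. S phase genes rose in 4 of 24 cases (0.0011, and adjusted p = 0.38 with an estimated correlation), and the interferon response in 3 of 6 (0.030, also adjusted p = 0.38 with an estimated correlation), with equal counts adjusted over the list alone. The S phase call ended without Troy-GFP library 1 (median 0.56). The Notch pathway (5 of 12), BMP and Id genes (5 of 10), Wnt pathway genes (6 of 13, with 1 higher), lipid metabolism (7 of 29, with 1 higher) and glycolysis (4 of 15) fell. They gave 0.0020, 0.0030, 0.00090, 0.0020 and 0.013, and adjusted p = 0.12, 0.18, 0.12, 0.12 and 0.43 with an estimated correlation; adjusted over the list alone, 6, 5, 9, 8 and 4 fell, with 1 Wnt and 1 lipid gene higher. The BMP call ended without Prom1/CD24 library 4 (-0.26), the Notch call without Troy-GFP library 2 (-1.09) or 4 (-1.28), and the Wnt call without Troy-GFP library 1 (-1.63), 2 (-1.45), 3 (-1.46) or 4 (-1.50). The glycolysis call ended without Prom1/CD24 library 2 (-0.37) or Troy-GFP library 2 (-0.21) or 4 (-0.17), and the interferon call without Prom1/CD24 library 1 (0.34) or 3 (0.08) or Troy-GFP library 1 (1.04), 2 (1.00) or 4 (0.93). Markers of ependymal cells, which line the ventricle, gave 0 of 6 passing genes, also adjusted over the list alone (0.24, and 0.0017 with a block for the library number). Activated NSC markers (2 of 14 higher, 1 lower), mature neuron markers (0 of 4) and oligodendrocyte precursor markers (1 of 6 lower) did not pass (0.45, 0.45 and 0.99; activated NSC median -0.02, mean 0.04), with the same counts adjusted over the list alone. The median of mature neuron markers turned from -0.22 to 1.91 at a minimum of 500 transcripts (adjusted p = 0.00048) and to 1.62 without the filter on low counts (adjusted p = 0.037), with 8 and 18 genes tested in place of 4. After thinning, 313 of 790 genes tested passed, and the endothelial, BMP, Wnt and glycolysis calls ended.

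The mixed day-60 sort against the day-60 SEZ sort asked what olfactory bulb progeny and O4-positive cells add to lineage-traced SEZ cells. Named oligodendrocyte genes were far higher in the mixed sort: the transcription factor genes Sox10 (8.06 ± 0.89) and Myrf (7.25 ± 0.69) and the myelin genes Mobp (7.33 ± 0.72) and Mbp (6.02 ± 0.35). The neuronal genes Gad1 (4.81 ± 0.19) and Snap25 (3.74 ± 0.22) rose too. Crym (-8.36 ± 0.82), the Wnt modulator Dkk3 (-6.19 ± 0.64) and Clu (-4.03 ± 0.15) fell. Slc1a3 gave -2.26 ± 0.19, Egfr -3.54 ± 0.49 and Tnfrsf19 -1.55 ± 0.23, all passing, and Cd24a did not pass (-0.14, limma adjusted p = 0.88). Its day-60 level hung on library 3, at 221 CPM against 10.7 to 34.3 in the other day-60 libraries. In all, 3528 of 8152 genes passed, 1806 higher and 1722 lower in the mixed sort. The gates differ between these sorts, and the mixed sort also held younger mice.

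Markers of oligodendrocytes (20 of 20 higher; Cnp 4.39 ± 0.21), oligodendrocyte precursors (11 of 12 higher, 1 lower; Olig1 4.01), mature neurons (13 of 14 higher) and neuroblasts (13 of 22 higher, 1 lower) rose, and all 22 quiescent NSC and astrocyte markers fell. They gave camera adjusted p of 4.6e-18, 9.1e-06, 8.3e-07, 9.1e-06 and 1.2e-20, and adjusted p = 0.087, 0.082, 0.082, 0.24 and 0.082 with an estimated correlation. Lipid metabolism (22 of 30 lower, 3 higher), the Notch pathway (10 of 13 lower; Hes5 -2.45), Wnt pathway genes (11 of 16 lower, 3 higher; Fzd2 -3.54) and BMP and Id genes (6 of 12 lower, 1 higher; Id4 -4.25) fell. They gave 1.4e-06, 5.0e-05, 0.0039 and 0.0085, and adjusted p = 0.21, 0.075, 0.082 and 0.25 with an estimated correlation. Ribosomal proteins rose in 28 of 76 cases with 1 lower (0.00011, and adjusted p = 0.59 with an estimated correlation). Glycolysis (6 of 16 lower, 2 higher), the interferon response (5 of 11 lower) and endothelial markers (5 of 10 lower) gave 0.031, 0.039 and 0.031, and adjusted p = 0.42, 0.42 and 0.59 with an estimated correlation. Those 3 calls ended under several settings; the interferon median turned from -0.68 to 0.20 after thinning, glycolysis lost its call without day-60 library 1 (-0.22), endothelium without mixed library 3 (-1.37) and the interferon response without mixed library 1 (-0.65) or day-60 library 2 (-0.56), 3 (-0.69) or 4 (-0.72). With p adjusted over the list alone, in the order given, 20, 11, 13, 15, 0, 3, 0, 3, 1, 26, 2, 0 and 0 genes rose and 0, 1, 0, 1, 22, 23, 10, 11, 6, 1, 6, 7 and 5 fell. Microglial (0.93; median 0.15, mean -0.03), activated NSC (0.63), pericyte and smooth muscle (0.58), S phase (0.53), G2 and M phase (0.72; median -0.49, mean 0.12) and immediate early genes (0.086) did not pass as lists. In these 0 of 13, 3 of 9, 1 of 4, 1 of 6, 5 of 14 and 6 of 25 genes rose and 0, 4, 1, 0, 5 and 1 fell; adjusted over the list alone, G2 and M phase gave 5 and 7, immediate early genes 5 and 1 and the rest the same counts. After thinning, 1041 of 1884 genes tested passed, and the calls of oligodendrocyte precursor markers and Wnt pathway genes ended too.

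**Figure D3:**
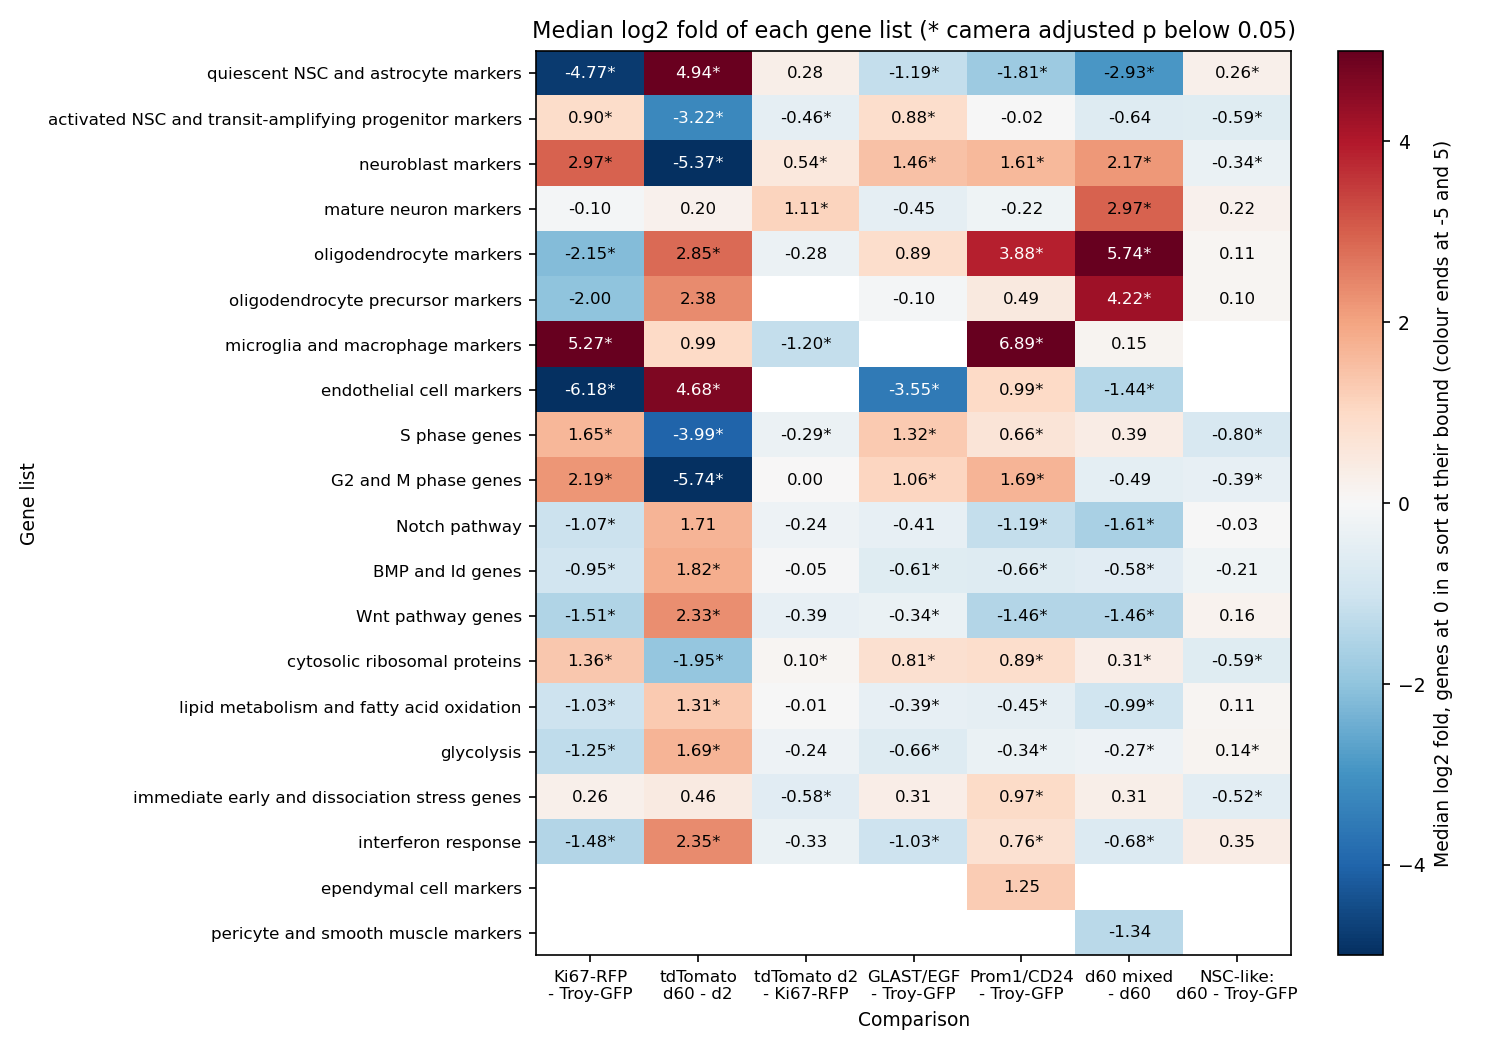
Each cell gives the median log2 fold of the tested genes of a list (vertical axis) in a comparison (horizontal axis), red for higher and blue for lower in the sort named first, with genes at 0 in a sort set at their bound from 3 transcripts; blank where fewer than 3 genes were tested. Asterisks mark camera adjusted p below 0.05 at the preset correlation of 0.01; 83 of 123 passed, and 7 with an estimated correlation.

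NSC-like cells of day-60 tdTomato against those of Troy-GFP asked how NSC-like cells of the labelled lineage compare with NSC-like cells of the Troy reporter. Both may include astrocytes that are not stem cells, since the NSC-like markers do not tell these apart. The day-60 cells held less Thbs4, a gene of the extracellular matrix that marks SEZ astrocytes (-3.19 ± 0.35, 36.5 against 308 CPM), and less of the neuroblast and progenitor genes Sox11 (-2.20 ± 0.37), Sox4 (-2.21) and Stmn1 (-1.67 ± 0.32). The call of Sox4 ended without day-60 library 2 (-2.48). The cyclin gene Ccnd2 gave -1.43 ± 0.23 and the amino acid transporter gene Slc38a1 -2.24 ± 0.42. Slitrk5, a gene of synapse formation (1.44 ± 0.25), and the homeobox gene Rhox8 (1.81 ± 0.25) rose. Among genes that met the limits for naming, Xist was the highest (8.18 ± 0.62). Of the passing genes 6.58% lay on the X or Y chromosome, against 3.61% of those tested. Tnfrsf19 (0.27 ± 0.18, limma adjusted p = 0.44), Egfr (-0.24, 0.52) and Slc1a3 (0.23 ± 0.07, 0.062) did not pass, and Cd24a did (-2.25 ± 0.67, 0.045), a call that ended without day-60 library 1 (-2.31), 2 (-2.25) or 4 (-1.56) or Troy-GFP library 1 (-2.18), 2 (-2.22) or 4 (-2.18). Of 6562 genes 319 passed, 162 higher and 157 lower at day 60, with 1201 at an unadjusted p below 0.05. Leaving out 1 library gave 204 without day-60 library 1, 196 without library 2, 212 without library 4 and 202 without Troy-GFP library 4. Within the flow cell HVJH2BGXX 198 passed, with the flow cell as a term 180, and after thinning 50 of 1290 genes tested.

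**Figure D4:**
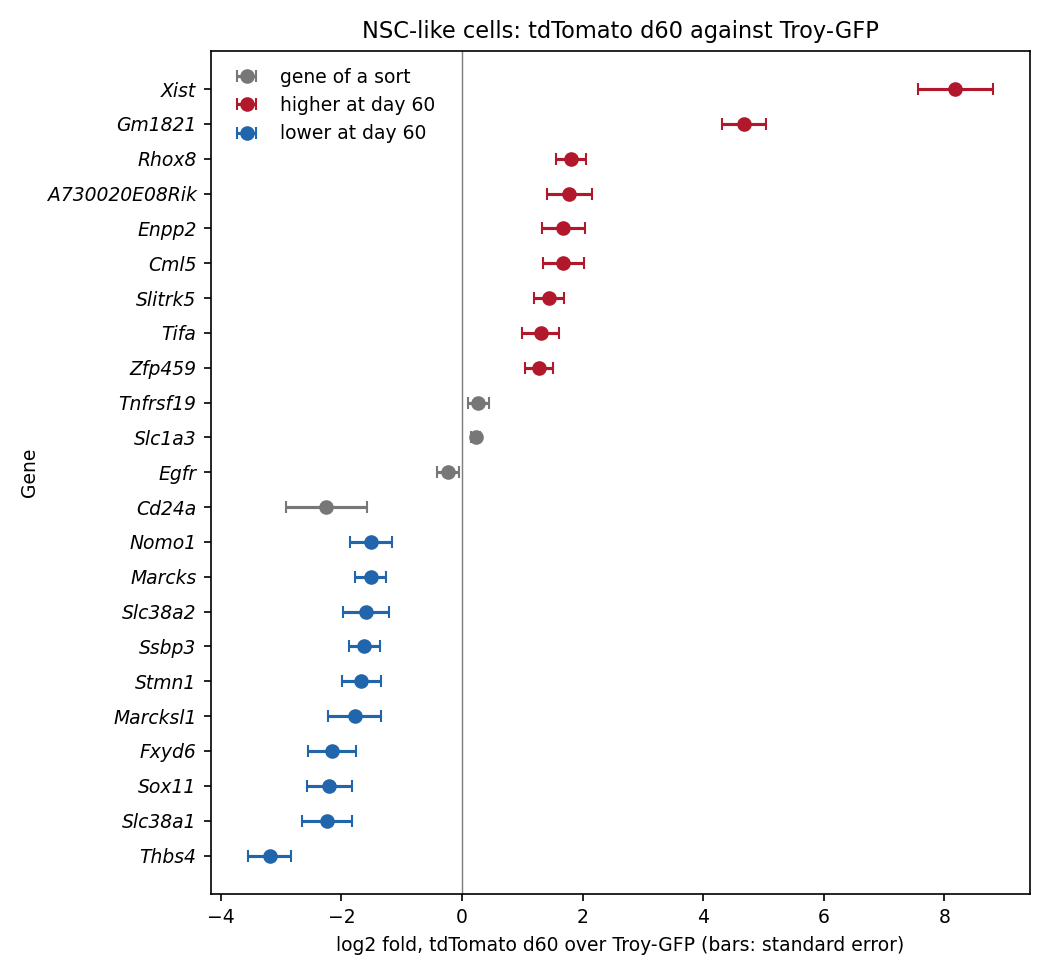
Points give the log2 fold of NSC-like cells, day-60 tdTomato over Troy-GFP, for genes among the 10 highest and 10 lowest and the sorts' genes that were tested; bars give the standard error (n = 4 libraries in each sort). Of the genes shown, Xist is the highest at 8.18 and Thbs4 the lowest at -3.19. The 10 highest and 10 lowest were taken among genes with a mean log2 CPM of at least 5. In all, 4 passing genes lay on the Y chromosome, where Ddx3y stood at 0 in every day-60 library.

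Among the lists, 9 of 24 quiescent NSC and astrocyte markers rose (the gap junction gene Gja1 0.59 ± 0.09) and 1, Thbs4, fell. Activated NSC and progenitor markers fell in 4 of 11 cases, and ribosomal protein genes in 41 of 76 (Rpl4 -1.01 ± 0.14). Camera adjusted p were 7.9e-08, 5.2e-06 and 8.4e-39, and adjusted p = 0.088, 0.088 and 0.17 with an estimated correlation. Neuroblast markers fell in 3 of 8 cases, S phase genes in 2 of 5, G2 and M phase genes in 5 of 13 (Tubb5 -1.21) and immediate early genes in 1 of 10. They gave 0.0022, 0.00063, 0.0051 and 0.00063, and adjusted p = 0.19, 0.19, 0.25 and 0.19 with an estimated correlation. Glycolysis passed as a list (0.038, and adjusted p = 0.30 with an estimated correlation) with 0 of 16 genes passing, and its call ended without day-60 library 1 (median 0.14) or 3 (0.10) or Troy-GFP library 1 (0.12) or 3 (0.12). The G2 and M phase call ended without Troy-GFP library 1 (median -0.26), and after thinning this call and those of activated NSC markers and immediate early genes ended. When adjusted over the list alone, in the order given, 15, 0, 0, 0, 0, 2, 0 and 0 genes rose and 1, 5, 55, 4, 4, 5, 3 and 0 fell. The Notch pathway (0 of 13 genes), BMP and Id genes (0 of 11), the interferon response (0 of 9), oligodendrocyte precursor markers (0 of 4), Wnt pathway genes (0 higher and 2 lower of 16), lipid metabolism (2 and 1 of 30), oligodendrocyte markers (2 and 1 of 8) and mature neuron markers (0 and 1 of 4) did not pass as lists. Their adjusted p were 0.63, 0.49, 0.081, 0.63, 0.95, 0.084, 0.49 and 0.95. Adjusted over the list alone, 0, 1, 0, 1, 2, 3, 2 and 2 genes rose and 0, 0, 0, 0, 3, 2, 2 and 1 fell. Median and mean differed in sign for Wnt pathway genes (0.16 and -0.08). Sort, sex and mouse line moved together in this comparison, and age with them.

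The share of NSC-like cells in cycle was read from G2 and M phase transcripts, after thinning to 1000 transcripts. At least 2 such transcripts were found in 58.4% ± 4.09 of day-60 and 64.6% ± 2.90 of Troy-GFP NSC-like cells (difference -6.23 points, exact 2-sided permutation p = 0.114). Oligodendrocyte-like and ependymal-like cells, which do not divide, gave 74.8% (113 of 151, 95% Clopper-Pearson interval 67.1 to 81.5), so both values lie at or below background. Median depths before thinning were 4996, 5520 and 5014 transcripts. Without day-60 library 1 the difference was -7.94 points (p = 0.0286 by the exact permutation test, the smallest it can give). A measure from mitotic genes alone, chosen after this, gave 2.83% ± 1.20 at day 60 and 5.07% ± 5.88 in Troy-GFP (difference -2.24 points, exact 2-sided permutation p = 0.457), with 2 of 151 background cells (1.32%).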

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

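Chosen only after the result was seen were thinning to 2000 and 3000 transcripts, the controls that drop other or fewer genes, the sets of multicopy and intestinal genes, the limit for gut-rich wells and the share of transcripts in them, and the check of the flow cell of the day-2 sort. At Leiden resolution 1.0, NSC-like cells of day-60 tdTomato lay apart from those of Troy-GFP. Of the day-60 cells, 91.5% fell in clusters where they outnumbered Troy-GFP cells at least 3 to 1. At resolution 0.5, 1 NSC-like cluster of 485 cells took the place of those of 224 and 247 cells, led by Eif2s3y and by Crym. The share apart was not computed at 0.5, so the separation may depend on the resolution. At resolution 1.0 without the 636 genes of the X and Y chromosomes, 76.8% of the day-60 cells lay apart. Sex-linked genes alone therefore do not account for the separation seen at that resolution. In the Troy-GFP libraries sharing the flow cell 9.40% of NSC-like cells (11 of 117) lay in the main day-60 cluster, against 0.813% (1 of 123) in the others, which argues against the flow cell as the whole cause but leaves a contribution open. Thinned to 1000 transcripts the share apart was 13.03%, which met the bound set for depth as the cause, but Troy-GFP cells apart also dropped, from 91.3% to 28.3%, so depth stays open, while 2000 and 3000 transcripts gave 81.1% and 77.1%. In GLAST/EGF, a sort of the same sex and age as Troy-GFP, 1 of 121 NSC-like cells lay in the main day-60 cluster. The clusters led by Eif2s3y and by Thbs4 held 62 and 47 of them. GLAST/EGF cells were not sorted as the day-60 cells were, so their placement cannot decide whether the day-60 sort placed cells there. The placement also moved: at the lower minimum of transcripts per cell, the cluster led by Crym held 11 GLAST/EGF, 31 Troy-GFP and 224 day-60 cells. Sex, age, mouse line and sort of the day-60 cells moved together and may each contribute. Effects of sex on other chromosomes, age, mouse line and sort were not tested apart.

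Day-2 tdTomato cells lay in clusters of their own in 94.1% of cases, while Ki67-RFP cells of the same classes lay elsewhere. After thinning, 90.9% still did, so depth does not account for it. As for a differing annotation, 0 genes stood at 50 CPM in 1 side and 0 in the other. That count misses any difference that leaves stray transcripts, so annotation stays open. Rn45s, for one, averaged 85.9 CPM at day 2 and 20545 to 68303 in the other sorts. Without 615 genes picked by symbol the value was 12.7%, against 94.1% to 94.5% in 5 draws of other genes of like expression, 89.1% without Rn45s, Rn4.5s and Lars2 alone and 94.1% without the other 612. Rn45s and Lars2 were put in that set for their folds, so the test decides nothing; whether reads of multicopy genes were counted in another way stays open, and remapping the reads of all sorts together would test it. A batch cannot be ruled out, since 0 libraries of other sorts are known to share its flow cell, and no biological explanation was tested.

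Transcripts of 22 intestinal genes, among them Lypd8, Reg1 and Ces2a, summed to 1606 in the 4 libraries of flow cell AHY73KBGXX (83.2 per 100000). Elsewhere they summed to 159 (1.83 per 100000). Of the 1606, 1122 (69.9%) lay in analysed cells. Those 4 libraries held 189 and 544 (GLAST/EGF 3 and 4) and 15 and 858 (Troy-GFP 1 and 2), in 53, 53, 15 and 67 wells. At a minimum of 500 transcripts 22 wells (17 Troy-GFP, 5 GLAST/EGF) formed a cluster led by Lypd8 and Reg1. Of these wells 3 held fewer than 1000 transcripts, and the rest were analysed cells. Counts per cell barcode correlated between GLAST/EGF 3 and 4 (rho of 0.594) but hardly between these and Troy-GFP 2 (0.0770 and 0.123; pairs with Troy-GFP 1 were not tested), which leaves reads of another library on that flow cell open. Only 1 well held at least 10% intestinal transcripts (10.3%), with 4.36% of those of that flow cell, and no analysed cell more than 1.70%, which argues against sorted gut cells as the source of most of them, though that well stays open. Reads of another library could have added them, and no biological explanation was tested.

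Of 116 groups of 4 libraries, 11 held a library far from the other 3, where chance gives 5.8, about 1 in 20 groups. Prom1/CD24 library 1 held 56.8% ERCC RNA (the others 44.3% to 46.2%; libraries of other sorts 6.57% to 17.7%). Shares of NSC-like cells stood apart in Ki67-RFP library 1 (1.32%, the others 2.41% to 2.63%) and Prom1/CD24 library 2 (30%, the others 9.09% to 12.5%). Shares of 0 stood apart for neuroblast-like cells in GLAST/EGF library 2 (others 4.84% to 5.77%), oligodendrocyte-like cells in GLAST/EGF library 1 (5.77% to 6.45%) and unnamed cells in Troy-GFP library 1 (1.20% to 1.39%). Slc1a3 was at 2943 CPM in Troy-GFP library 4 (3185 to 3233), Prom1 at 35.02 in mixed library 4 (0 to 4.48), and Cd24a at 452 in GLAST/EGF library 3 (278 to 306) and 221 in day-60 library 3 (10.7 to 34.3). Troy-GFP library 2 had 68.97% NSC-like cells with G2 and M phase transcripts (62.96% to 63.5%). Outside the analysed cells, 109 Prom1/CD24 wells of 500 to 1000 transcripts, and 0 of other sorts, fell in a cluster led by Lrrc17, Ddn and Camk2a.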

How the results depend on the processing

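A term for the flow cell, limma-trend, Rn45s left out, mitotic genes alone and NSC-like GLAST/EGF against Troy-GFP were chosen after results were seen. With each comparison counted once per setting, 66 counts of passing genes stayed within 1.5 times and 13 moved (50 and 6 with 1 library left out). Named gene results, again once per setting, kept direction and call 6458 times, lost the call 176, gained it 36 and reversed 5 times (4618, 204, 33 and 0 with 1 library left out). For list results these were 1418, 143, 37 and 3 (927, 31, 17 and 1). Class shares passed under no setting; the shares themselves moved, in Ki67-RFP from 62.4% to 16.4% neuroblast-like (the cause was not tested). Thinning to 1000 transcripts left 1197 genes (Ki67-RFP against Troy-GFP), 1247 (day 60 against day 2), 402 (day 2 against Ki67-RFP), 274 (GLAST/EGF), 313 (Prom1/CD24), 1041 (mixed sort) and 50 (NSC-like cells), with fewer genes tested; it shows how far depth limits these counts. The flow cell HVJH2BGXX alone gave 1024 (GLAST/EGF), 779 (Prom1/CD24) and 198 (NSC-like), with fewer libraries. For Prom1/CD24 no filter gave 4582, with more genes tested, and all sorts in 1 fit 2246; NSC-like cells gave 180 with the flow cell as a term (the cause was not tested). Leaving out 1 library gave 958 to 1536 (Prom1/CD24), 196 to 307 (NSC-like) and -7.94 to -4.61 points for cycling. With an estimated correlation 7 of 83 list calls held. The library number as a block gave 4925, 5082, 1986, 2173, 1365, 3371 and 373 genes, in the order of the report; pairs correlated at -0.0798 to 0.0652, so the numbers do not pair the libraries. Directions turned, the cause was not tested: microglial markers (day 2 against Ki67-RFP; -1.59 to 0.11 with 1 library left out), mature neuron markers in Prom1/CD24 (-0.22; 1.62 without filter, 1.91 at 500 transcripts), Ndrg4 there (-0.13; 1.63 at 500), the interferon list in the mixed sort (-0.68; 0.20 thinned) and H2-K1 there (-0.38; 0.20 thinned), Vcan in Ki67-RFP (0.08; -0.63 in HVJH2BGXX alone and with the flow cell as a term) and Rrm2 at day 2 (0.64; -0.029 thinned).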

Other observations

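Chosen only after results were seen were the comparison of NSC-like GLAST/EGF and Troy-GFP cells and the RNA content of classes. Clusters within the classes set neurons and rarer cells apart. Mature neuron-like cells formed a cluster of 57 cells marked by Calb2, Th and Trh, genes of olfactory bulb interneurons, and another of 35 marked by Nrip3, Pcp4 and Penk. Unnamed clusters were marked by Gzma, Ccl5 and Nkg7, genes of cytotoxic lymphocytes (24 cells), by Dcn, Vtn and Col1a2, genes of stromal cells (25), by Npy and Frzb (19) and by Ttr, Kcnj13 and Clic6, genes of choroid plexus (12). Among NSC-like cells, 60.5% ± 8.52 of Troy-GFP cells lay in a cluster led by the Y-linked gene Eif2s3y, with Ddx3y, also Y-linked, Hopx, Mertk and Gdf10 among its 10 leading genes, and 30.7% ± 4.16 in 1 marked by Thbs4, Notum and Gfap (n = 4 libraries). Of day-60 NSC-like cells, 79.8% ± 6.55 lay in a cluster marked by Crym, Fjx1 and Hapln1. At Leiden resolution 0.5, 1 cluster of 485 NSC-like cells took the place of this cluster and that led by Eif2s3y. Relative to ERCC RNA, progenitor-like cells held 2.19-fold the transcripts of NSC-like cells in GLAST/EGF (1.93 to 2.48 over 4 libraries) and 2.20-fold in Troy-GFP (1.70 to 2.65), in 4 of 4 libraries each (exact 2-sided permutation p = 0.125, the smallest possible).

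NSC-like cells of GLAST/EGF against those of Troy-GFP gave 22 passing genes of 5403 with limma, 13 higher and 9 lower (706 at an unadjusted p below 0.05). Egfr (1.05 ± 0.22, adjusted p = 0.0405) and the histone chaperone gene Nasp (1.21 ± 0.27) rose, and Clu (-0.86 ± 0.16) and Gdf10 (-1.71 ± 0.39) fell (n = 4 libraries each). Counts were 27 with the flow cell as a term, 0 of 4384 within the flow cell HVJH2BGXX (2 against 2 libraries, 227 unadjusted), 82 and 29 at minimums of 500 and 2000 transcripts, and 22 at Leiden resolution 0.5.

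Other groupings of the libraries were tried for each of the 7 comparisons. In each, 1 of 35 splits, the real one, gave as many passing genes. The highest count of another split was 2 for Prom1/CD24 against Troy-GFP, 1 for NSC-like cells and 0 in the others. Every other split mixed libraries of both sorts, which put the sort difference within each group, so low counts there were bound to follow. The lowest level 4 against 4 libraries allow is 1 in 35. These splits cannot exclude chance differences between mice or plates, since the libraries of a sort may share 1 plate.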
